A study of Mus musculus with 18 samples.

How the data were processed

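RNA from skeletal muscle, heart and hippocampus of transgenic and wild type C57BL/6 mice had been hybridised to 18 Affymetrix arrays, 3 for each genotype in each tissue, and every array entered the analysis. The deposited values are on the log2 scale, 1 value per probe set and array. They were made by RMA (background correction, normalization between arrays and summary of the probes of a set) in R 2.10.0, per the submitters' processing notes. The chip definition, any filter, and whether all arrays were normalized together are not given in the sources used here. Array medians differed between tissues by more than within them (2.44 to 2.49 in skeletal muscle, 2.61 to 2.63 in heart, 3.68 to 3.71 in hippocampus), so levels set across tissues carry a shift of the whole array that the comparisons within a tissue do not. Groups were taken from the sample labels.

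The table held 35382 probe sets. The platform annotation gave 1 gene symbol for 21153 of them, covering 18781 symbols, several for 1867 and none for 12362. By Entrez ID, 21123 of the probe sets with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. All probe sets were tested, and genes were named from those with 1 symbol. Where a gene had several probe sets, the fixed candidate genes and the members of gene lists were taken from the probe set with the highest mean over all arrays. No probe set was named for the transgene.

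Every comparison came from 1 limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 6 groups, fitted to the values as deposited. Its 12 residual degrees of freedom were shared by all groups, with 2.67 more from the empirical Bayes prior. The SE of a gene in 1 tissue therefore also reflects its spread in the other tissues, including those where its signal was low. Transgenic arrays were compared with wild type arrays in each tissue. The mean of the 3 genotype differences, the interaction of genotype and tissue (moderated F test) and the tissues of wild type mice were also tested. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of a comparison were called, and all tests were two-sided. Of 43 gene lists drawn up beforehand, 42 had at least 5 measured genes. The lists held 808 members, of which 735 were measured. Each list was tested with limma's cameraPR, which compares its moderated t statistics with those of all other genes, at a preset correlation between genes of 0.01. Adjustment ran over the lists of a comparison. Each list was tested again with the correlation estimated from its own residuals, and with fry, which tests whether the members moved, on balance, 1 way. Fry's separate test for change in either direction is given only where it is named.

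Genes were named by a fixed rule. In each genotype comparison it took up to 12 called genes in each direction by the size of the difference, or the 10 with the smallest unadjusted p where fewer than 10 passed. It took up to 12 in each direction by adjusted p for the mean difference, 10 for the interaction, and the 6 highest and 6 lowest for each pair of tissues. For each list described it took up to 4 members with the smallest unadjusted p, and it added a fixed set of calcium handling, troponin C, heart, activity and sex-linked genes. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

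The alternatives tried were other sets of arrays in the fit, the replicate number as a block, the same number in different tissues as a random block, leaving out the dimmer probe sets or those without a single symbol, centring or quantile normalization of the arrays, an intensity trend with a robust prior, array quality weights, other thresholds, and leaving out each array in turn. The procedure was tested on simulated data with the spread of each probe set in the fit to all arrays, the same in every tissue. With 50 of 35382 probe sets changed at each size, it called 19 at a log2 change of 0.5, 41 at 1, 44 at 1.5 and 46 at 2, and made 9 false calls in the simulated heart comparison. Figures were drawn with matplotlib 3.10.9.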

Results

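TN-XXL is a genetically encoded calcium indicator in which a calcium-binding domain taken from troponin C lies between a cyan and a yellow fluorescent protein, so that bound calcium alters the energy transfer between them. Transcript levels were measured in skeletal muscle, heart and hippocampus of mice that carried this transgene and of wild type littermates, in a design that crossed genotype with tissue. The 18 arrays formed 6 groups of 3. The labels number the arrays within a group without saying whether arrays of different tissues came from the same animals, so p-values measure only the spread between these samples, which can be technical. The number of arrays limits the precision of the values. Pairs of arrays from the same group correlated at 0.982 to 0.993 across probe sets. Genotype differences are transgenic minus wild type on the log2 scale, with the SE of the fit and n = 3 arrays in each group. Expression of the transgene itself was not analysed here. Of the endogenous troponin C genes, Tnnc2 in skeletal muscle stood at 11.10 ± 0.05 (SD) in transgenic and 11.12 ± 0.09 in wild type arrays, and Tnnc1 in heart at 10.59 ± 0.04 and 10.78 ± 0.11. Neither passed (adjusted p = 0.967 and 0.762, and 0.953 and 0.513 with only the arrays of the tissue), although all 3 transgenic heart arrays lay below all 3 wild type heart arrays for Tnnc1. By chance the groups stand apart, in either direction, in 10% of cases.

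In skeletal muscle, the core genes of the circadian clock moved apart between the genotypes. Arntl, which encodes the clock activator BMAL1, was 6.67-fold lower in transgenic muscle, at 2.93 ± 0.29 against 5.67 ± 0.26 in wild type (SD, difference −2.74 ± 0.17, adjusted p = 1.68e-07). Npas2, which encodes a partner of BMAL1, fell by 1.95 ± 0.17 (adjusted p = 3.68e-06). The period genes Per1, Per2 and Per3, whose products repress that activator, rose by 2.11 ± 0.21, 2.32 ± 0.18 and 2.06 ± 0.20, and the clock repressor Ciart rose by 2.90 ± 0.29. Of the 16 measured clock genes 8 rose, 5 fell and 3 did not pass; adjusted over the list alone, 9 rose and 5 fell. The list as a whole passed the camera test (adjusted p = 0.00806) but not with the correlation estimated (adjusted p = 0.264 with an estimated correlation).

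Outside the clock, Mt2, the gene of a metal-binding metallothionein, stood at 9.90 ± 0.11 in transgenic and 6.86 ± 0.39 in wild type arrays (SD, 8.23-fold, adjusted p = 1.97e-05). Tmem28 rose by 2.86 ± 0.13, BC051142 by 2.78 ± 0.13, the probe set named for Mir675, a microRNA made from the imprinted H19 transcript, by 2.59 ± 0.23, Ift27, a component of intraflagellar transport, by 2.57 ± 0.17, Snai3 by 2.56 ± 0.16, the nuclear receptor gene Nr4a3 by 2.35 ± 0.26 and the adenylate kinase gene Ak4 by 2.27 ± 0.23 (1.09 by its other probe set, adjusted p = 0.00165). Whether the probe set of Mir675 reports the microRNA or the H19 transcript was not tested. Adcy2, an adenylyl cyclase gene, fell by 2.66 ± 0.12, 1700001O22Rik fell by 3.08 ± 0.22, the potassium channel subunit gene Kcnf1 fell by 2.53 ± 0.28, Gm4861 fell by 2.52 ± 0.20, and Slc16a10, which encodes a transporter of aromatic amino acids, fell by 2.38 ± 0.11. Cish, a target and inhibitor of cytokine signalling through STAT5, fell by 2.15 ± 0.23, Ttll7 fell by 2.11 ± 0.14, Odc1, the rate-limiting enzyme gene of polyamine synthesis, fell by 2.05 ± 0.16, Adhfe1 fell by 1.99 ± 0.11 and Neto2 fell by 1.98 ± 0.34. The lower mean of Ciart, BC051142, 1700001O22Rik, Kcnf1, Gm4861 and Neto2 lay under the median of the muscle arrays (2.45), so the exact sizes of these differences are not read. In all, limma called 2884 of 35382 probe sets in muscle (1364 higher and 1520 lower), of which 1289 differed by at least 1.5-fold. When only the muscle arrays entered the fit, 838 were called, and 145 to 279 with 1 of those arrays left out as well.

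Of the 29 genes of calcium buffers and calmodulin signalling measured in muscle 6 fell, 1 rose and 22 did not pass; adjusted over the list alone, 8 fell and 1 rose. Rcan1 and Rcan2, which encode regulators of calcineurin, fell by 0.98 ± 0.13 and fell by 0.80 ± 0.09. Ppp3cb, a catalytic subunit of calcineurin, fell by 0.88 ± 0.09, the calmodulin gene Calm3 fell by 0.54 ± 0.09 (adjusted p = 0.00129), and Nfatc2, a transcription factor that calcineurin activates, rose by 0.88 ± 0.10. Camk2a fell by 0.48 ± 0.11 (adjusted p = 0.0121), a call that ended without array 2 of the wild type group (0.0595). At the preset correlation the list passed (adjusted p = 0.0359, adjusted p = 0.264 with an estimated correlation), as it did by fry (3.31e-04). It did not pass without array 3 of the transgenic group (0.0522), with only the muscle arrays in the fit (0.064), with the mean of all probe sets of a gene (0.0667) or without the dimmer probe sets (0.103). Among 24 genes of plasma membrane and store calcium transport 4 fell and 1 rose (6 and 1 adjusted over the list alone), with the calcium pump gene Atp2b3 at −1.31 ± 0.14 and the store sensor gene Stim2 at −0.66 ± 0.10, and the list did not pass (adjusted p = 0.0646). Without transgenic array 2 the counts were 2 and 2, and none rose without wild type array 1 or 2 or transgenic array 1. Among 26 genes of excitation-contraction coupling 3 rose and 3 fell (3 and 6 adjusted over the list alone, list adjusted p = 0.188), including the calcium channel subunit gene Cacna2d1 at −0.90 ± 0.12. Of these, 1 rose without wild type array 1 or 2 or transgenic array 1 or 3, and 1 fell without wild type array 3. Abundant genes of fast muscle calcium handling did not pass, with Ryr1 at −0.11 ± 0.07 (adjusted p = 0.455), Atp2a1 at −0.11 ± 0.20 (0.846) and Pvalb at 0.04 ± 0.10 (0.897). For Ryr1 and Atp2a1 all 3 transgenic muscle arrays lay below all 3 wild type muscle arrays, where chance sets the groups apart, in either direction, in 10% of cases. Neither gene passed with only the muscle arrays in the fit (adjusted p = 0.626 and 0.586). Of 16 fast fibre genes only Mylk2, a myosin light chain kinase gene, passed (−0.83 ± 0.16), and neither the fast nor the slow fibre list passed (adjusted p = 0.818 and 0.973). The slow fibre gene Myl2 was called, but not with only the muscle arrays in the fit (adjusted p = 0.33). The fast fibre list had a median of 0.02 and a mean of −0.04, on either side of 0.

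Metabolic and stress genes also shifted in muscle. Of 42 genes of oxidative phosphorylation 11 rose and 31 did not pass (15 rose adjusted over the list alone), among them the complex I genes Ndufb5 at 0.50 ± 0.09 and Ndufa1 at 0.43 ± 0.07. Without transgenic array 3, 7 rose. Their list passed at adjusted p = 2.08e-04 (adjusted p = 0.283 with an estimated correlation). Of 27 ribosomal protein genes 6 rose and 21 did not pass (9 rose adjusted over the list alone), with Rpl3 at 0.72 ± 0.10 and a list adjusted p of 2.08e-04 (adjusted p = 0.259 with an estimated correlation). The 6 probe sets of Rpl3 differed by 0.70 to 0.74. In the antioxidant list, 7 of 17 genes fell and 1 rose (9 and 1 adjusted over the list alone). Without wild type array 2 or 3 or transgenic array 3, 4 fell. The glutathione synthesis gene Gclm fell by 1.04 ± 0.07, the glutathione transferase gene Gstm2 fell by 1.20 ± 0.12, the quinone reductase gene Nqo1 fell by 1.13 ± 0.15, and Gpx1, a glutathione peroxidase gene, rose by 1.05 ± 0.12. This list passed at adjusted p = 2.08e-04 (adjusted p = 0.264 with an estimated correlation). Fatty acid oxidation genes fell in 6 cases of 25 and rose in 1 (8 and 3 adjusted over the list alone). None rose without wild type array 1 or 2 or transgenic array 1 or 2. Mlycd, which encodes malonyl-CoA decarboxylase, was 2.82-fold lower (adjusted p = 4.76e-06), Etfa, an electron transfer flavoprotein gene, fell by 0.79 ± 0.08, and the lipoprotein lipase gene Lpl fell by 0.74 ± 0.12. That list passed at adjusted p = 0.00806 (adjusted p = 0.476 with an estimated correlation), and not without array 3 of the wild type (0.133) or of the transgenic group (0.0514).

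Glucocorticoid-responsive genes rose in 5 of 15 cases in muscle and fell in 1 (9 and 1 adjusted over the list alone), with the metallothionein gene Mt1 at 1.22 ± 0.19 and the inhibitor of NF-kB gene Nfkbia at 0.93 ± 0.19 beside Per1 and Mt2. Without wild type array 3, 8 rose. The list passed at adjusted p = 0.00406 (adjusted p = 0.492 with an estimated correlation). Of 23 immediate early genes, which respond rapidly to stimulation, 5 rose and 1 fell (8 and 1 adjusted over the list alone). Egr1 rose by 1.03 ± 0.20, Junb rose by 0.50 ± 0.10 and Homer1 fell by 0.66 ± 0.10. Without transgenic array 1 or 2, 3 rose. Their list passed at adjusted p = 0.0123 (adjusted p = 0.297 with an estimated correlation) and not without array 1 of the wild type group (0.0576). Endothelial markers fell in 4 of 14 cases (6 adjusted over the list alone), with the receptor gene Tek at −0.72 ± 0.11 and Egfl7 at −0.56 ± 0.13, beside the metabolic shifts. Only 2 fell without wild type array 1 or transgenic array 2 or 3, where Emcn (adjusted p = 0.0719, 0.0636 and 0.156) and Cldn5 (0.101, 0.0588 and 0.161) did not pass. This list passed at adjusted p = 0.00806 (adjusted p = 0.348 with an estimated correlation) and not without array 3 of the transgenic group (0.065). In the unfolded protein response list 3 of 19 genes fell and 1 rose (9 and 1 adjusted over the list alone). Only 1 fell without wild type array 2 or transgenic array 2, where Dnajc3 (adjusted p = 0.116 and 0.095) and Chac1 (0.0826 and 0.117) did not pass. The endoplasmic reticulum chaperone gene Hspa5 fell by 0.50 ± 0.09, the asparagine synthetase gene Asns rose by 0.61 ± 0.11, and the list passed at adjusted p = 0.0214 (adjusted p = 0.259 with an estimated correlation). With only the muscle arrays in the fit 43 of 68 named calls in muscle passed. Those on Neto2 (adjusted p = 0.109), Calm3 (0.1), Camk2a (0.0649), Ndufa1 (0.0634), Junb (0.0605), Egr1 (0.0773), Nfkbia (0.0925), Egfl7 (0.166), Hspa5 (0.0644) and Asns (0.103) did not. In that fit 1 gene of oxidative phosphorylation, 1 ribosomal protein gene and 0 genes of the unfolded protein response were called.

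In heart, the same clock genes stood out. Arntl fell from 5.58 ± 0.04 in wild type to 3.01 ± 0.29 in transgenic arrays (SD, difference −2.57 ± 0.17, adjusted p = 1.89e-06), Npas2 fell by 1.75 ± 0.17, and Nfil3, a clock-controlled repressor gene, fell by 1.88 ± 0.22. Ciart rose by 2.69 ± 0.29, Per3 by 2.54 ± 0.20, Per2 by 2.29 ± 0.18 and Per1 by 2.07 ± 0.21, and Wee1, a cell cycle kinase gene that the clock controls, rose by 1.88 ± 0.21. Of the 16 clock genes 11 rose, 4 fell and 1 did not pass, the same counts as when adjusted over the list alone. As a whole the list passed at adjusted p = 8.67e-14 (adjusted p = 0.0482 with an estimated correlation). Of the clock genes, 12 were called in both muscle and heart.

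**Figure D1:**
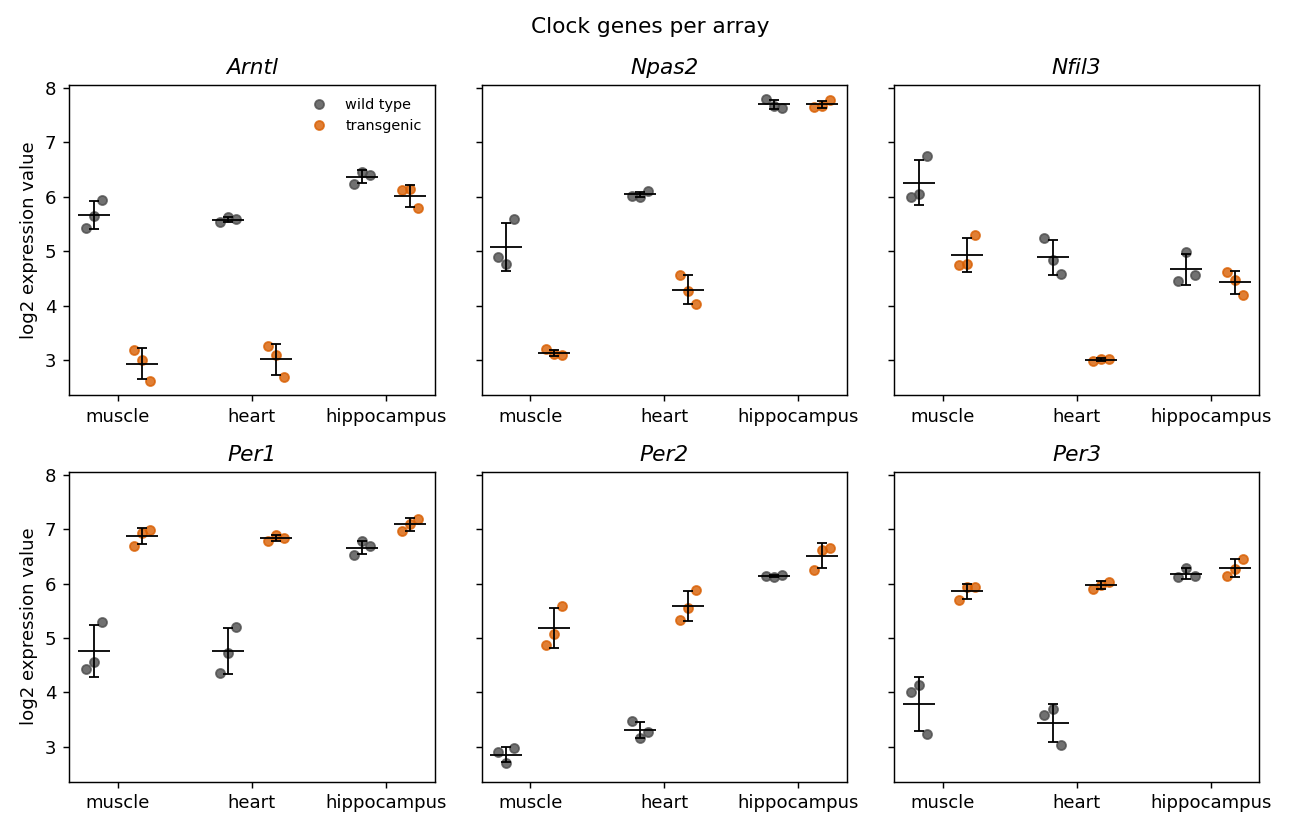
Log2 expression of 6 clock genes on every array, with 3 tissues along the horizontal axis and wild type and transgenic arrays side by side; points are single arrays and bars show the mean ± SD of 3. In muscle and heart Arntl lay lower in transgenic arrays, by 2.74 and 2.57, and Per2 higher, by 2.32 and 2.29, and in hippocampus the differences were −0.35 and 0.37.

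Further genes changed in heart. Tlcd4 rose by 2.53 ± 0.15 (adjusted p = 8.51e-07), the potassium channel gene Kcnk1 by 2.35 ± 0.30, Armh4 by 2.06 ± 0.14, Ddit4l, an inhibitor of mTOR signalling, by 1.94 ± 0.26, and Nmrk2, which encodes a nicotinamide riboside kinase, by 1.76 ± 0.17. The metalloprotease gene Adam19 fell by 1.90 ± 0.22, Fam124b fell by 1.78 ± 0.26, Spon2 fell by 1.65 ± 0.29, Fah, the last enzyme of tyrosine breakdown, fell by 1.60 ± 0.18, Tmem171 fell by 1.52 ± 0.20, Mfsd4b1 fell by 1.45 ± 0.13, the semaphorin receptor gene Plxnb1 fell by 1.44 ± 0.11 and Mfsd4b3-ps fell by 1.42 ± 0.19. Arrdc2 (2.21 ± 0.49), Gm12250 (1.79 ± 0.37) and 1 of the 19 probe sets of Trdn (−1.28 ± 0.26) also passed. The call on Arrdc2 ended without wild type array 1 or 2 or transgenic array 2 or 3 (adjusted p = 0.0964, 0.0813, 0.0707 and 0.104), that on Gm12250 without wild type array 1 or 3 (0.0586 and 0.0575) and that on Trdn without wild type array 2 or transgenic array 3 (0.0672 and 0.0744). The lower mean of Tlcd4, Kcnk1, Gm12250 and Fam124b lay under the median of the heart arrays (2.62), with the same limit on their sizes. A probe set shared by several genes rose by 3.59 and is not named. In all, limma called 1128 probe sets (556 higher and 572 lower), 488 of them by at least 1.5-fold. The count fell to 669 without wild type array 1, 746 without wild type array 2, 701 without transgenic array 2 and 593 without transgenic array 3, and to 36 when only the heart arrays entered the fit. In that fit 15 of 56 named calls in heart passed. They were those on Arntl, Npas2, Nfil3, Nr1d2, Ciart, Per1, Per2, Per3, Tlcd4, Armh4, Nmrk2, Fam124b, Mfsd4b1, Plxnb1 and Myl1. The others had an adjusted p of 0.052 to 0.279.

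Markers of atrial muscle, stress and excitability moved in heart. Nppa, the atrial natriuretic peptide gene, stood at 11.06 ± 0.22 in transgenic and 9.70 ± 0.21 in wild type arrays (SD, 2.57-fold, adjusted p = 1.87e-04), and Kcnj3, an atrial potassium channel gene, rose by 0.84 ± 0.10. These were 2 of 12 measured atrial markers; none fell, and adjusted over the list alone 3 rose. The atrial list passed at adjusted p = 1.94e-04 (adjusted p = 0.207 with an estimated correlation). Nppb, the other stress-induced natriuretic peptide gene, stood at −0.52 ± 0.17 and did not pass (adjusted p = 0.126). In the list of cardiac stress and hypertrophy 5 of 15 genes fell and only Nppa rose (8 fell and 2 rose adjusted over the list alone). The skeletal actin gene Acta1 fell by 1.18 ± 0.23, the matricellular gene Ccn1 fell by 1.06 ± 0.18, and Rcan1 fell by 1.08 ± 0.13. Without wild type array 2 or 3 or transgenic array 1 or 2, 3 fell. This list passed at adjusted p = 0.044 (adjusted p = 0.345 with an estimated correlation), but not without wild type array 2 (0.209) or transgenic array 1 (0.151) or 2 (0.0582), nor without the dimmer probe sets (0.11). Of 17 genes of cardiac ion channels and conduction 4 fell (7 fell and 1 rose adjusted over the list alone). Gja1, which encodes the gap junction protein connexin 43, fell by 0.74 ± 0.11, and Kcnip2, a potassium channel subunit gene, fell by 0.73 ± 0.09. The other calls, on Hcn2 and Kcne1, ended without wild type array 1 (adjusted p = 0.071 and 0.0682) or 3 (0.107 and 0.108) or transgenic array 2 (0.114 and 0.123) or 3 (0.0733 and 0.0574), which left 2. This list passed at adjusted p = 0.00174 (adjusted p = 0.0684 with an estimated correlation). Endothelial markers moved with these groups, with 2 of 14 lower (7 adjusted over the list alone) and a list median of −0.29 (adjusted p = 9.36e-04, adjusted p = 0.332 with an estimated correlation). Both calls, on Tek and Cldn5, ended without wild type array 1 (adjusted p = 0.069 and 0.112), 2 (0.0559 and 0.0677) or 3 (0.0831 and 0.108) or transgenic array 2 (0.0624 and 0.105) or 3 (0.107 and 0.159), which left 0. With only the heart arrays in the fit 0 genes of the atrial, stress, conduction and endothelial lists were called.

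Among contractile and calcium handling genes of the heart, the ryanodine receptor gene Ryr2 fell by 0.38 ± 0.07 (adjusted p = 0.00971), the calcium channel subunit gene Cacnb1 fell by 0.42 ± 0.07, Myl1, a fast myosin light chain gene, rose by 1.52 ± 0.19, and the slow myosin gene Myh7b fell by 1.04 ± 0.18. With only the heart arrays in the fit the calls on Ryr2 (adjusted p = 0.146), Cacnb1 (0.142) and Myh7b (0.117) ended. The lists of excitation-contraction coupling (1 of 26 rose and 2 fell, 2 and 2 adjusted over the list alone) and of calcium buffers and calmodulin signalling (2 of 29 fell, 3 fell and 2 rose adjusted over the list alone) did not pass (adjusted p = 0.541 and 0.958). The rise, that of the sodium-calcium exchanger gene Slc8a3, ended without wild type array 1 (0.064) or 2 (0.06) or transgenic array 2 (0.0502) or 3 (0.054). The fall of Calr, which encodes the calcium-binding chaperone calreticulin, ended without wild type array 1 (0.0677) or transgenic array 3 (0.0553).

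Protein folding and turnover genes shifted in heart. Of 19 genes of the unfolded protein response 9 fell, 1 rose and 9 did not pass (10 fell and 2 rose adjusted over the list alone). Sdf2l1 fell by 1.18 ± 0.17, Hspa5 fell by 0.65 ± 0.09, Xbp1, a transcription factor of the response, fell by 0.64 ± 0.09, and the chaperone gene Hsp90b1 fell by 0.54 ± 0.09. Without wild type array 1 or transgenic array 3, 6 fell and 0 rose, and 0 were called with only the heart arrays in the fit. The list passed at adjusted p = 7.03e-07 (adjusted p = 0.0482 with an estimated correlation). Of 25 proteasome genes only Psma1 rose (0.37 ± 0.07, adjusted p = 0.0115), a call that ended without transgenic array 2 (0.052), and 7 rose adjusted over the list alone. The proteasome list passed at adjusted p = 7.92e-04 (adjusted p = 0.207 with an estimated correlation). Glucocorticoid-responsive genes rose in 3 of 15 cases (6 adjusted over the list alone), namely Per1, Klf9 at 0.56 ± 0.11 and Mt2 at 1.42 ± 0.32. Without transgenic array 1, 5 rose. The list passed at adjusted p = 7.03e-07 (adjusted p = 0.328 with an estimated correlation). The heart call on Mt2 (adjusted p = 0.0247) ended without wild type array 1 or 2 or transgenic array 2 or 3 (0.0961, 0.0881, 0.0668 and 0.105). Of 25 fatty acid oxidation genes 2 fell (2 fell and 1 rose adjusted over the list alone), of which Mlycd fell by 1.18 ± 0.13 and Etfa fell by 0.73 ± 0.08. Their list passed at adjusted p = 0.0451 (adjusted p = 0.625 with an estimated correlation), but not without wild type array 2 (0.115) or 3 (0.0702) or transgenic array 3 (0.178). It passed in 4 of 13 alternatives, and not by fry (0.0904), with only the heart arrays (0.073), with the mean of all probe sets of a gene (0.0502) or without the dimmer probe sets (0.11).

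The remaining heart lists that passed rested on small shifts or on single arrays. None of 19 interferon response genes and none of 14 antigen presentation genes was called, although 18 and 12 had positive differences, as for Ifit3 (0.79 ± 0.24) and H2-K1 (0.76 ± 0.22). Both lists had an adjusted p of 0.00938 (adjusted p = 0.357 and 0.455 with an estimated correlation) and did not pass without transgenic array 2 (0.268 and 0.249). None of 42 oxidative phosphorylation genes was called, with a list median of 0.08 (adjusted p = 0.00974, adjusted p = 0.502 with an estimated correlation), and the list did not pass without wild type array 1 (0.0792) or 3 (0.0694). Of 20 muscle atrophy genes 2 rose (4 rose and 1 fell adjusted over the list alone), Mt2 and the translation inhibitor gene Eif4ebp1 at 0.58 ± 0.09. Only Eif4ebp1 rose where the call on Mt2 ended. That list passed at adjusted p = 0.0187 (adjusted p = 0.621 with an estimated correlation), and not without wild type array 1 (0.137) or 2 (0.0511) or transgenic array 2 (0.0682) or 3 (0.0914). The p53 and apoptosis list, with 2 of 14 genes higher (2 adjusted over the list alone), passed at adjusted p = 0.043 (adjusted p = 0.18 with an estimated correlation), and not without wild type array 1 (0.0813) or 2 (0.124) or transgenic array 1 (0.0769) or 2 (0.0753). The called genes were Mdm2 and Trp53inp1, and neither was called without wild type array 2 (0.0576 and 0.0676) or transgenic array 3 (0.0689 and 0.076). The call on Mdm2 also ended without any other 1 of the 6 heart arrays (0.0527 to 0.0936).

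In hippocampus, limma called 0 probe sets, and 1784 of 35382 had an unadjusted p under 0.05, close to the number that chance gives at that threshold. The smallest adjusted p was 0.19, for Klhdc7b, at 3.08 ± 0.05 in transgenic and 2.54 ± 0.09 in wild type arrays (SD), both under the median of the hippocampus arrays (3.70). The next by unadjusted p were the chemokine gene Ccl17 (0.74 ± 0.13, adjusted p = 0.326), the cardiac actin gene Actc1 (−0.56 ± 0.11, 0.402) and the RNA sensor gene Tlr7 (0.76 ± 0.15, 0.402), followed by Adamts17 (−0.50 ± 0.10, and −0.38 to −0.16 by its other probe sets), Adssl1 (0.48 ± 0.10), Cckar (0.46 ± 0.09), Ephx1 (0.54 ± 0.11), Rfx2 (−0.51 ± 0.11) and Zfy1 (−0.42 ± 0.09). The abundant kinase gene Camk2a differed by 0.01 ± 0.11 and the astrocyte gene Gfap by −0.01 ± 0.10. With array quality weights 1 probe set was called.

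Some gene lists passed in hippocampus at the preset correlation although no single gene did, and none passed by fry or with the correlation estimated. The immediate early genes, which neurons induce with activity, had positive differences in 20 of 23 cases (list median 0.25), and 5 rose when adjusted over the list alone. Egr1 stood at 0.72 ± 0.20, Nr4a1 at 0.66 ± 0.21, Arc at 0.52 ± 0.25, Fos at 0.46 ± 0.19, Junb at 0.44 ± 0.10 and Fosb at 0.43 ± 0.09. The list passed at adjusted p = 1.01e-09 (adjusted p = 0.15 with an estimated correlation). Glucocorticoid-responsive genes had positive differences in 14 of 15 cases (1 rose adjusted over the list alone), with Nfkbia at 0.70 ± 0.19 and the kinase gene Sgk1 at 0.57 ± 0.20, and passed at adjusted p = 5.97e-06 (adjusted p = 0.333 with an estimated correlation). Unfolded protein response genes had negative differences in 14 of 19 cases (3 fell adjusted over the list alone), with Hspa5 at −0.34 ± 0.09, and passed at adjusted p = 3.26e-04 (adjusted p = 0.163 with an estimated correlation). Myelin and oligodendrocyte genes stood higher by a median of 0.22, with Mag at 0.33 ± 0.14 (adjusted p = 0.00872, adjusted p = 0.333 with an estimated correlation), and the list did not pass without wild type array 1 (0.161) or transgenic array 2 (0.431). Smooth muscle and pericyte genes (median 0.12, Acta2 at 0.43 ± 0.11, adjusted p = 0.016) and the cardiac stress list (median 0.06, Nfkbia and Ace its leading members, adjusted p = 0.0113) each had an adjusted p = 0.285 with an estimated correlation. The smooth muscle list did not pass without wild type array 1 (0.0989) or 2 (0.25) or transgenic array 1 (0.0839), nor the cardiac stress list without wild type array 1 (0.0871) or 2 (0.0616). Ribosomal protein genes (median 0.06, adjusted p = 0.0237, adjusted p = 0.369 with an estimated correlation) did not pass without wild type array 1 (0.12) or 3 (0.236) or transgenic array 2 (0.192). The clock list (Ciart at 0.87 ± 0.29 and, by its other probe set, at 0.33, list adjusted p = 0.0485, adjusted p = 0.333 with an estimated correlation) did not pass without wild type array 1 (0.0989) or 3 (0.236) or transgenic array 2 (0.255) or 3 (0.13). By fry, 0 lists passed in hippocampus. With limma's cameraPR 8 lists passed, but 4 without wild type array 1 and 5 without transgenic array 2.

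**Figure D2:**
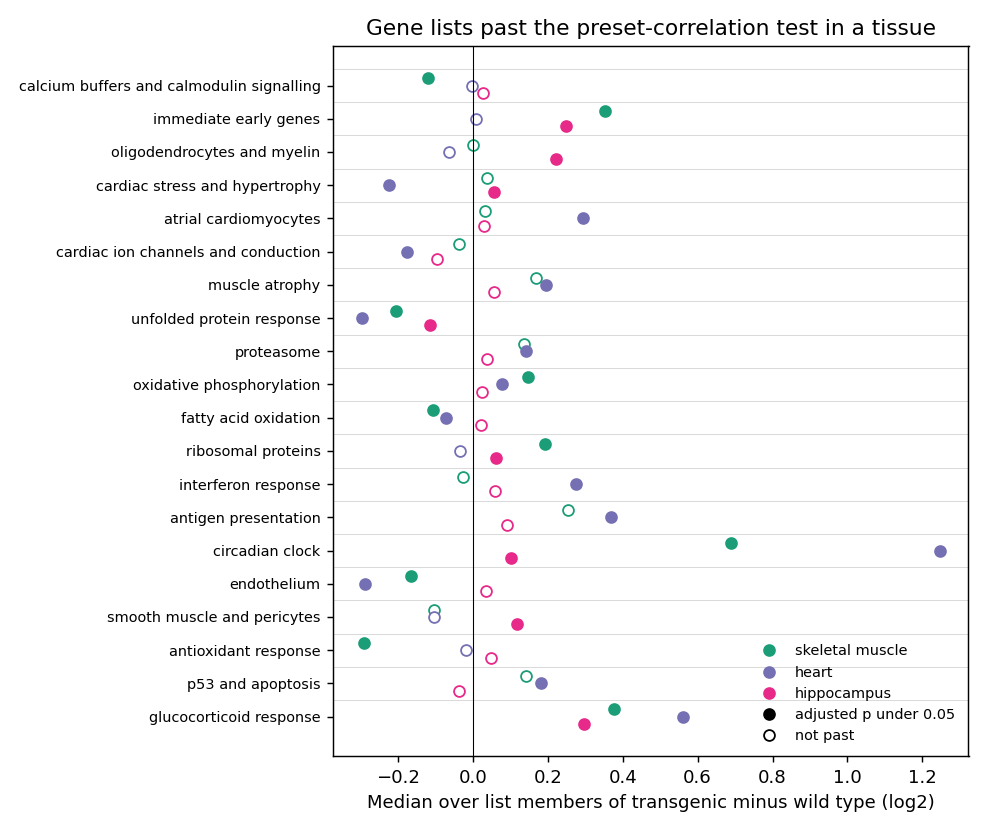
Median log2 difference (transgenic minus wild type) of the genes of each list, 1 symbol per tissue, filled where the list passed at the preset correlation of 0.01. The clock list reached 0.69 in muscle, 1.25 in heart and 0.10 in hippocampus, and the unfolded protein response list lay below 0 in all 3 tissues, at −0.21, −0.30 and −0.12.

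Averaged over the 3 tissues, the genotype difference was called for 2052 probe sets (915 higher and 1137 lower), 196 of them by at least 1.5-fold. The mean can pass without agreement among the tissues. Examples below are Adcy2 (−2.66 in muscle, −0.42 in heart and 0.07 in hippocampus) and Mfsd4b1 (−1.77, −1.45 and 0.06 in the same order). Among probe sets with 1 gene symbol the smallest adjusted p belonged to Arntl (−1.89 ± 0.10, 9.20e-08) and to Btbd2 (−0.81 ± 0.04, 9.20e-08). Usp2, a deubiquitinase gene under clock control, rose by a mean of 0.79 ± 0.05 (2.18e-07), Per2 by 1.66 ± 0.10, Per3 by 1.57 ± 0.12, Per1 by 1.54 ± 0.12, Ciart by 2.15 ± 0.17 and the clock repressor gene Nr1d2 by 0.88 ± 0.07. Metabolic genes among the highest ranks were Fbp2, a gluconeogenic enzyme gene of muscle (0.79 ± 0.05), the pyruvate dehydrogenase kinase gene Pdk3 (0.76 ± 0.06) and Nmrk2 (1.26 ± 0.10), together with Fbxo36 (1.19 ± 0.09), BC051142 (1.13 ± 0.08) and the kinase gene Mapk10 (0.76 ± 0.05). Lower on average were Adhfe1 (−1.09 ± 0.06), Mfsd4b1 (−1.05 ± 0.07), Adcy2 (adjusted p = 1.46e-06), Slc16a10 (−0.92 ± 0.06), the heparan sulfate proteoglycan gene Gpc1 (−0.88 ± 0.05), Ypel2 (−0.83 ± 0.06), the mitochondrial fatty acid synthesis gene Mecr (−0.74 ± 0.05), Mllt1 (−0.73 ± 0.06), Skiv2l (−0.67 ± 0.05) and the coenzyme Q synthesis gene Coq2 (−0.65 ± 0.05). Across lists, 10 of 19 unfolded protein response genes fell (11 fell and 2 rose adjusted over the list alone, adjusted p = 1.59e-07, adjusted p = 0.0604 with an estimated correlation), and 7 of 15 glucocorticoid-responsive genes rose (10 rose and 1 fell adjusted over the list alone, adjusted p = 2.24e-09, adjusted p = 0.218 with an estimated correlation).

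Muscle and heart shared part of their calls. Of the probe sets called in both tissues 160 were higher in both, against 21.4 for independent lists, 218 were lower in both, against 24.6, and 36 went in opposite directions. No expected number was computed for opposite directions. Both lists used the same estimate of the spread of a probe set, so the numbers for independent lists are not the level that chance gives. Ddit4l was among those in opposite directions, at 1.94 in heart and −1.81 in muscle. The heart calls had the sign of the muscle difference in 846 of 1128 cases (75%) and that of the hippocampus difference in 658. Across 35382 probe sets, which are not independent replicates, the differences in muscle and heart correlated with r = 0.186 (Spearman's rho 0.163), those in muscle and hippocampus with r = 0.007 and those in heart and hippocampus with r = 0.03. These comparisons share no arrays.

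**Figure D3:**
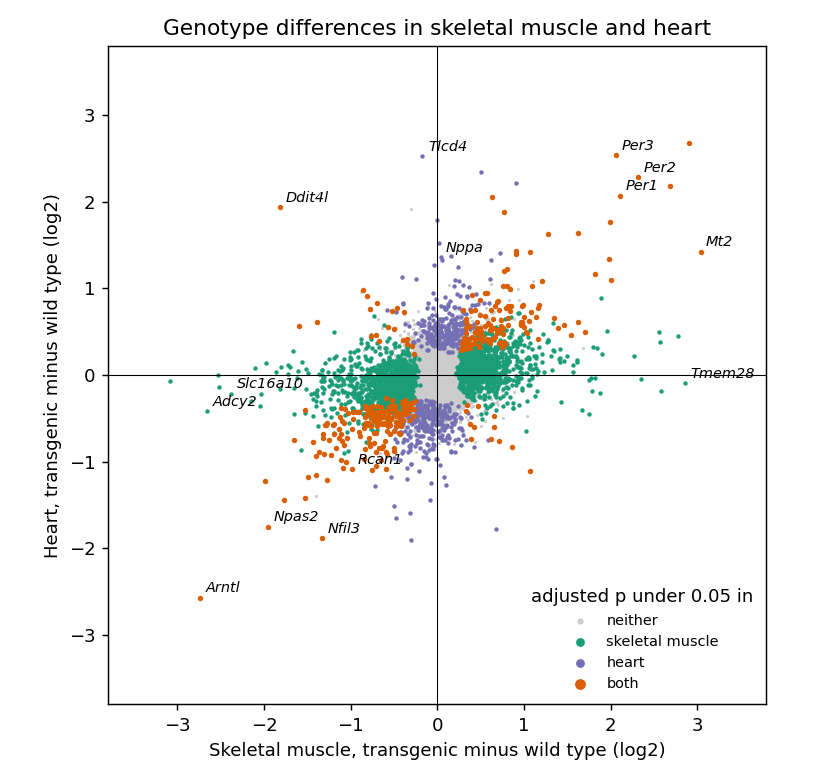
Log2 difference between genotypes in heart (vertical axis) against that in skeletal muscle (horizontal axis), 1 point for each probe set with a single gene symbol, coloured by whether it was called in neither tissue, in muscle, in heart or in both. Clock genes lie at the far ends of the shared direction, with Arntl at −2.74 and −2.57 and Ciart at 2.90 and 2.69.

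The genotype difference itself differed between tissues for 1376 probe sets by the interaction test. The strongest were Tmem28 (2.86 in muscle, −0.09 in heart, −0.16 in hippocampus, adjusted p = 8.36e-07), Adcy2 (−2.66, −0.42 and 0.07 in the same order, 2.97e-06), the kinase gene Cdk19 (−1.86, 0.04 and 0.02, 2.97e-06) and Slc16a10 (−2.38, −0.21 and −0.17, 3.01e-06). The next were BC051142, Tlcd4, Fhl2, Ell2, Sv2b and Mdga1 (adjusted p from 5.81e-06 to 2.31e-05), of which Tlcd4 differed in heart by 2.70 more than in muscle and Fhl2, a LIM domain gene of cardiac muscle, by 2.09 less (−2.09). The exact sizes for Tlcd4 and BC051142 are not read, since their lower mean lay under the median of the arrays. For Arntl, Per2, Per3 and Npas2 the tissue effects differed as well (adjusted p = 6.93e-05, 3.71e-04, 3.90e-04 and 3.81e-04), with the widest gap between hippocampus and either muscle or heart. Taken in pairs, 903 probe sets differed in effect between heart and muscle, 1204 between hippocampus and muscle and 206 between hippocampus and heart. Of 126 differences of list shifts between tissues, 20 passed at the preset correlation and 0 with the correlation estimated (lowest adjusted p = 0.127).

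Between the tissues of wild type mice, genes were taken by the size of the fitted difference among probe sets with 1 gene symbol. For these genes the mean of the lower tissue lay under the median of that tissue's arrays in 11 of 12 cases between heart and muscle and in 12 of 12 for each comparison with hippocampus. Signal over background was not analysed here, so only their direction is read, and neither their exact sizes nor their order. Heart exceeded skeletal muscle in the cardiac sarcomere genes Mybpc3 (9.56 ± 0.12) and Tnni3 (9.33 ± 0.09), in Ryr2 (8.60 ± 0.07), in the desmosome gene Dsp (8.38 ± 0.11), in Nppa (7.84 ± 0.15) and in Fhl2 (7.80 ± 0.11), and lay below it in the fast muscle genes Pvalb (−9.71 ± 0.10), Atp2a1 (−9.62 ± 0.20), Actn3 (−9.58 ± 0.21), Myh4 (−9.53 ± 0.12), Tnnt3 (−9.24 ± 0.17) and Ryr1 (−9.05 ± 0.07). Hippocampus exceeded muscle in the synaptic vesicle genes Snap25 (9.51 ± 0.09) and Syt1 (9.47 ± 0.12), in Aldoc (9.45 ± 0.09), in the neuronal calcium sensor gene Hpca (9.34 ± 0.08), in the glutamate receptor gene Gria1 (9.22 ± 0.10) and in the glutamate transporter gene Slc17a7 (9.21 ± 0.12). It lay below muscle in Atp2a1 (−9.46 ± 0.20), Myot (−9.20 ± 0.10), Myh4 (−8.98 ± 0.12), the creatine kinase gene Ckm (−8.91 ± 0.11), Mybpc2 (−8.79 ± 0.22) and Car3 (−8.72 ± 0.16). Against heart, hippocampus was higher in Aldoc (9.45 ± 0.09), Hpca (9.40 ± 0.08), Snap25 (9.18 ± 0.09), the calcium sensor gene Vsnl1 (9.18 ± 0.15), Syt1 (9.02 ± 0.12) and Gria1 (9.01 ± 0.10), and lower in Myl3 (−8.92 ± 0.21), the myoglobin gene Mb (−8.78 ± 0.07), Mybpc3 (−8.65 ± 0.12), Myl2 (−8.59 ± 0.16), Tnni3 (−8.38 ± 0.09) and Myoz2 (−8.25 ± 0.15).

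Of the probe sets, limma called 13697 between heart and muscle (9049 higher in heart and 4648 lower), 27667 between hippocampus and muscle (24800 and 2867) and 27165 between hippocampus and heart (23817 and 3348). The median difference over all probe sets was 0.07, 0.68 and 0.61, so most of the calls with hippocampus lay on the side of a shift of whole arrays. The share of calls on the higher side was 66.1%, 89.6% and 87.7% as deposited. It was 44.0%, 26.4% and 26.0% after each array was centred on its median, and 50.7%, 43.3% and 44.2% after quantile normalization of all arrays together. In the muscle genotype comparison, centring moved that share from 47.3% to 41.4%.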

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

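The tests of clock genes, of the shared estimate of spread, of fibre type genes and of glucocorticoid-responsive genes were chosen after the results were seen. Genotype differences that differed between tissues were picked out by the interaction test, which passed for 1376 probe sets. Of 214 named genes tested, 99 probe sets passed, against 1376 of 35382 over all probe sets. Many of these genes had been named for large differences in 1 tissue or for the interaction itself, so their higher share is built in. Each is given by the widest of its 3 gaps between tissues, as the log2 genotype difference in the first tissue minus that in the second. Taking the widest gap favours large values. The gap was widest between hippocampus and skeletal muscle for 55, between heart and skeletal muscle for 24 and between hippocampus and heart for 20. Exact gaps and their order are not read for genes with a mean under the median of a tissue's arrays. Among these are 1700001O22Rik, Kcnf1, Neto2, Tlcd4, Fam124b, Kcnk1, BC051142, Gm4861 and Ciart.

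For hippocampus minus skeletal muscle the gap was positive for Adcy2 (2.73), Gm4861 (2.43), Arntl (2.39), Odc1 (2.28), Cish (2.24), Slc16a10 (2.20), Npas2 (1.95), Adhfe1 (1.93), Mfsd4b1 (1.83), Ell2 (1.81), Mfsd4b3-ps (1.54), Gpc1 (1.41), Atp2b3 (1.36), Ypel2 (1.28), Nqo1 (1.21), Mlycd (1.18), Btbd2 (1.17), Gstm2 (1.13), Skiv2l (1.11), Cacna2d1 (1.09), Gclm (1.08), Mllt1 (1.06), Coq2 (1.04), Mecr (1.03), Ppp3cb (0.92), Tek (0.87), Adssl1 (0.84), Etfa (0.81), Homer1 (0.72), Stim2 (0.64), Cckar (0.58), Calm3 (0.56) and Acadl (0.55). It was negative for Tmem28 (−3.01), Mt2 (−2.82), Ift27 (−2.66), BC051142 (−2.63), Snai3 (−2.48), Ak4 (−2.29), Ciart (−2.03), Nmrk2 (−1.97), Per2 (−1.95), Pdk3 (−1.70), Per1 (−1.69), Mapk10 (−1.63), Fbp2 (−1.49), Gadd45a (−1.12), Actc1 (−1.04), Nfatc2 (−1.01), Rfx2 (−0.96), Gpx1 (−0.92), Adamts17 (−0.86), Usp2 (−0.83), Rpl3 (−0.63) and Ndufa1 (−0.60).

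For heart minus skeletal muscle the gap was positive for Ddit4l (3.75), 1700001O22Rik (3.01), Tlcd4 (2.70), Kcnf1 (2.53), Ttll7 (2.19), Sv2b (2.16), Neto2 (2.12), Cdk19 (1.90), Mdga1 (1.84), Chac1 (1.42), Camk2a (0.86), Rcan2 (0.84) and Bcl2l11 (0.66). It was negative for Mir675 (−2.78), Fam124b (−2.46), Nr4a3 (−2.40), Fhl2 (−2.09), Egr1 (−1.67), Acta1 (−1.26), Myh7b (−1.07), Asns (−0.72), Xbp1 (−0.66), Cacna1c (−0.48) and Cacnb1 (−0.46).

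For hippocampus minus heart the gap was positive for Trdn (1.93, by 1 of its 19 probe sets), Adam19 (1.82), Nfil3 (1.65), Fah (1.55), Plxnb1 (1.48), Ccn1 (1.45), Tmem171 (1.39), Rcan1 (1.08), Gja1 (0.86), Klhdc7b (0.73) and Kcnip2 (0.68). It was negative for Per3 (−2.44), Kcnk1 (−2.38), Armh4 (−2.13), Wee1 (−1.91), Myl1 (−1.60), Nppa (−1.45), Fbxo36 (−1.34), Nr1d2 (−1.07) and Kcnj3 (−0.65). Nppa lay under the median of the hippocampus arrays in both genotypes, so a change there may not show.

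Of 126 gene list differences between tissues 20 passed at the preset correlation and 0 with the correlation estimated, and their values are medians over the genes of the differences of genotype effects. Heart minus skeletal muscle gave plasma membrane and store calcium transport (0.094), glycolysis (−0.15), ribosomal proteins (−0.25) and antioxidant response (0.22). Hippocampus minus skeletal muscle gave calcium buffers and calmodulin signalling (0.16), oxidative phosphorylation (−0.10), fatty acid oxidation (0.14), ribosomal proteins (−0.11), endothelium (0.22) and antioxidant response (0.36). Hippocampus minus heart gave immediate early genes (0.29), oligodendrocytes and myelin (0.31), cardiac stress and hypertrophy (0.31), atrial cardiomyocytes (−0.23), unfolded protein response (0.21), heat shock (0.17), proteasome (−0.079), circadian clock (−0.98), endothelium (0.19) and smooth muscle and pericytes (0.24).

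The first pattern weighed is that some clock genes rose and others fell, in the same way in skeletal muscle and heart. A single array apart from the rest is argued against, since at least 11 clock genes were called in both tissues without any 1 array, against 12 with all arrays. A shift of whole arrays is argued against as well, since clock genes moved both ways and the median difference of all probe sets was 0.016 in muscle and 0.003 in heart. The 16 clock genes lay a median distance of 0.98 in muscle and 1.58 in heart from that median. Random sets of 16 genes gave 0.21 and 0.19 at the 95th percentile. That comparison adds little, since the clock genes were already known to differ strongly when it was chosen. A candidate explanation is that tissue was taken at different times of day. It would move each clock gene the same way in both tissues, and 16 of 16 had the same sign in muscle and heart, and 13 of 16 in all 3 tissues. That count restates the pattern, so it does not favour this explanation over another. Collection times are not given in the sources used here, so a change of the clock by the transgene and a difference in collection time cannot be told apart.

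The second pattern is the larger count in skeletal muscle than in the other tissues. The 3 tissues shared 1 estimate of the spread per probe set, and this as the whole cause is argued against, since muscle still had the most calls with only the arrays of each tissue in its own fit (838, against 36 in heart and 0 in hippocampus). Without any 1 array these fits called at least 145 in muscle and at most 2 in heart and 0 in hippocampus. Another fibre type make-up of the dissected muscle stays open, since the fast minus slow difference of list means was −0.045 between genotypes, with an interval of −0.65 to 0.56 from the spread of the 6 arrays that reaches past the bound of 0.5 on either side (permutation p = 0.9, where 0.1 is the smallest possible). The fast minus slow values varied more among transgenic (SD 0.37) than among wild type arrays (SD 0.09). An effect of the transgene that is larger in muscle was not tested apart from these.

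The third pattern is the higher level of glucocorticoid-responsive genes in all 3 tissues. The clock genes within the list as its whole cause are argued against, since the highest adjusted p of the 3 tissues was 0.0354 without them. A single array is argued against by the highest adjusted p of 0.0416 without any 1 array. Both hold at the preset correlation, and the list passed in none of the 3 tissues with the correlation estimated (adjusted p = 0.492 in muscle, 0.328 in heart and 0.333 in hippocampus). Stress or time of collection may underlie it and was not tested here.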

How the results depend on the processing

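Quantile normalization of all arrays together and the lists without clock genes were chosen after seeing the data, and the other alternatives were planned. No named call changed sign with only the arrays of the tissue, the replicate block, the dimmer probe sets left out, quantile normalization within tissues, an intensity trend with a robust prior or 1 array left out, and named genes were not recomputed under the other alternatives. The balance of higher and lower calls between wild type tissues turned with the scaling. Calls on the higher side made up 66.1% between heart and muscle, 89.6% between hippocampus and muscle and 87.7% between hippocampus and heart as deposited, and 44.0%, 26.4% and 26.0% with each array centred. After quantile normalization of all arrays they made up 50.7%, 43.3% and 44.2%. Where only the arrays of the tissue entered the fit, 838 probe sets were called in skeletal muscle and 36 in heart, with fewer residual degrees of freedom by construction. At least 1.5-fold was reached by 1289 in muscle, 488 in heart, 196 for the mean difference and 8171 between heart and muscle of wild type mice. At an adjusted p under 0.1, 1786 were called in heart and 2176 by the interaction test. Leaving out the dimmer probe sets gave 15467 calls between hippocampus and muscle and 15073 between hippocampus and heart, and keeping those with 1 gene symbol gave 18401 between hippocampus and muscle, with fewer probe sets tested. Quantile normalization of all arrays gave 17223 between hippocampus and heart, and array quality weights called 1 probe set in hippocampus; the cause was not tested.

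With the correlation estimated, 0 lists passed in muscle, 2 in heart (clock and unfolded protein response) and 0 in hippocampus, against 10, 14 and 8 at the preset correlation. By fry 0 lists passed in hippocampus, and in heart those of muscle atrophy (adjusted p = 0.169), oxidative phosphorylation (0.056), fatty acid oxidation (0.0904), interferon response (0.0762) and antigen presentation (0.129) did not. Without the dimmer probe sets 6 lists passed in muscle, where those of the unfolded protein response, calmodulin signalling, fatty acid oxidation and endothelium no longer did, nor did those of cardiac stress (0.11), fatty acid oxidation (0.11) and p53 (0.0551) in heart and of the clock in hippocampus (0.0878). With the mean of all probe sets of a gene the lists of calmodulin signalling in muscle (0.0667), fatty acid oxidation in heart (0.0502) and the clock in hippocampus (0.0774) did not pass. The cause was not tested.

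Leaving out each array in turn gave 2262 to 2643 calls in muscle, 593 to 989 in heart, 0 to 0 in hippocampus, 1611 to 2015 for the mean difference, 929 to 1316 for the interaction, 12282 to 12704 between heart and muscle, 26305 to 26572 between hippocampus and muscle and 25782 to 26201 between hippocampus and heart. Lists passing ran from 9 to 13 in muscle, 10 to 12 in heart and 4 to 12 in hippocampus. In heart the count moved most without wild type array 1 (669) or 2 (746) or transgenic array 2 (701) or 3 (593), and in hippocampus without wild type array 1 (4 lists) or transgenic array 2 (5). Of 124 named calls, 58 passed with only the arrays of the tissue, 122 after quantile normalization within tissues and 124 with an intensity trend and robust prior, and 658 of 744 values without 1 array passed.

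The replicate numbers were not shown to pair the arrays, since deviations of arrays with the same number correlated between −0.05 and 0.05. With the replicate number as a block, 525 probe sets were called in heart, 2107 in muscle, 0 in hippocampus, 1360 for the mean difference and 570 by the interaction test, and 103 of 124 named calls passed. Of the lists, calmodulin signalling in muscle (adjusted p = 0.053) and fatty acid oxidation (0.0502) and cardiac stress (0.277) in heart did not pass with the block. As a random block across tissues the same number gave a correlation of −0.003.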

Other observations

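The tests of linked genes and of correlation between tissues were chosen after the results were seen, and the counts of splits were planned. Several lists not described so far held called genes in skeletal muscle without passing as a whole. In that tissue 2884 of 35382 probe sets and 2224 of 18781 gene symbols were called. A list of any genes would thus hold some calls, and counts of 1 or 2 are not read as a result about a list. Adipocyte markers had a median of 0.49, with 2 of 14 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.148, adjusted p = 0.492 with an estimated correlation). None rose without array 3 of either group. Antigen presentation genes had positive differences in 14 of 14 cases with a median of 0.26, and 1 rose (1 adjusted over the list alone, adjusted p = 0.117). None was called without array 1 or 2 of either group. Of 20 muscle atrophy genes 2 rose and 3 fell (7 and 5 adjusted over the list alone, adjusted p = 0.562), and fry's test for change in either direction gave an adjusted p of 1.68e-11. In this list 4 rose and 2 fell without wild type array 3, and 5 rose and 2 fell without transgenic array 1. Of 14 genes of p53 and apoptosis 3 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.0719), and by fry, which does not compare a list with other genes, it passed at adjusted p = 2.96e-04. The fall ended without array 3 of either group. In the same tissue 2 of 19 glycolysis genes rose (3 adjusted over the list alone) and the list did not pass (adjusted p = 0.0698). Genes of muscle denervation and regeneration rose in 4 and fell in 3 of 20 cases (5 and 4 adjusted over the list alone, adjusted p = 0.891, and 8.92e-12 by fry for change in either direction), with 2 higher without wild type array 1 or 2 or transgenic array 1, and 2 of 17 markers of microglia and macrophages rose (3 adjusted over the list alone, adjusted p = 0.0772), or 4 without wild type array 1. In hippocampus the excitatory synapse list (median 0.03, adjusted p = 0.295) and the reactive astrocyte list (median 0.06, adjusted p = 0.32) did not pass, and 0 of their 21 and 16 genes were called by limma.

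The sex-linked genes Xist, Kdm5d and Uty did not pass between genotypes in any of the 3 tissues. Xist, expressed from the inactive X chromosome of females, had group means of 1.58 to 2.17, and the Y-linked genes Eif2s3y, Kdm5d and Uty had group means of 5.37 to 6.87, 4.29 to 6.20 and 4.73 to 5.53. Eif2s3y stood higher in transgenic arrays by 0.47, 0.49 and 0.61 in muscle, heart and hippocampus, and passed in none (adjusted p = 0.187, 0.228 and 0.799).

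Genes next to the insertion site of a transgene can differ between littermates in every tissue. This was tested with a window of 100 neighbouring genes, a design changed after the values had been seen. The fullest window held 19 of the 1574 genes called for the mean difference, where random draws gave a median of 20 and a 95th percentile of 23 (permutation p = 0.856, 1000 draws), so a cluster of such calls was not detected, although a segment with few called genes would escape this test. A change in 1 tissue can be enough for a call on the mean difference. Genes that differ in every tissue were not tested apart, so the test cannot decide on a linked segment. Picked out after their values were seen, Mfsd4b1 (−1.77 in muscle, −1.45 in heart, 0.06 in hippocampus), the related pseudogene Mfsd4b3-ps (−1.53, −1.42 and 0.02) and Slc16a10 (−2.38, −0.21 and −0.17) lie close together in GRCm38.p6, and sequence shared by the related pair can bring their values together.

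Other splits of the arrays were counted. With 10 splits of 6 arrays the share cannot be under 0.05. The real split called 2884 probe sets in muscle, where the highest other split called 4, 1128 in heart (1), 0 in hippocampus, where all 10 splits called 0, 13697 between heart and muscle (1), 27667 between hippocampus and muscle (0) and 27165 between hippocampus and heart (0). For the next results genotype was reassigned in each tissue on its own. This is apt only if the tissues came from different animals, which the labels do not say. For the mean difference 1 of 100 drawn reassignments of genotype, the real one, called as many as 2052. On that condition chance can be excluded at 0.05. The highest other draw called 1947. That draw mirrored the labels of muscle and heart together. For the interaction 2 of 100 called as many as 1376, the real one and one with 2384 that mirrored muscle and kept heart as labelled. On the same condition, chance without a genotype difference in any tissue can be excluded at 0.05. These reassignments also break up a difference that the tissues share. They therefore cannot decide whether the genotype difference varies between tissues. The 65 draws in which no tissue was as labelled or mirrored called at most 2 and 1. For the correlation of the muscle and heart differences (0.186), 1 of 100 combinations of splits was as large, and the highest other was 0.131. If the same animals gave all tissues, the labels would move together, and with 10 such splits no share could be under 0.05.

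Some named genes had a dimmer second probe set that did not pass. In heart those of Plxnb1 and Klf9, at means of 2.16 and 3.10 over all arrays, differed by 0.05 and 0.04 (adjusted p = 0.909 and 0.972), and that of Nr1d2, at a mean of 1.92, by 0.02. In muscle that of Mapk10, at a mean of 2.27, differed by 0.02 (adjusted p = 0.979), and that of Ndufb5, at a mean of 3.04, by 0.34 (adjusted p = 0.268), in the direction of the first (0.50).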
